A study of Mus musculus with 24 samples.

How the data were processed

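The labels describe 24 samples of brain cortex from C57BL/6 mouse embryos in 8 groups. At each of 4 stages (E11.5, E13.5, E15.5 and E17.5) there are 3 RNA immunoprecipitations with an antibody against STAU2, a double-stranded RNA-binding protein, and 3 inputs. Per the labels' protocols, RNA was depleted of ribosomal RNA with Ribo-Zero and libraries were made with ScriptSeq, a kit that marks the strand.

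The table analysed here holds 18975 rows over 13879 merged peaks, with 12 columns of whole-number counts, which the authors deposited per peak and strand. The submitters' processing notes name HOMER 4.10 and the builds mm10 and GRCm38. The aligner, the counting tool, the settings of peak calling and any scaling before counting are not given in the sources used here. The authors also deposited a peak score for each merged peak, which was used here only to set a stricter selection of peaks. The 12 columns carry a stage and a replicate number that the labels give to both an immunoprecipitation and its input. They were read as the immunoprecipitations because the table lists peaks, and every result below rests on that reading. Input libraries were not analysed here, so comparisons of immunoprecipitation with input, and stage changes adjusted for input, were not run. A change between stages therefore mixes a change in the amount of an RNA with a change in its binding.

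The 14297 rows with a gene (7970 gene identifiers) were analysed. All 4513 rows called Intergenic were left out: they hold even numbers in every library, and the 606 that share a peak and strand with a gene row are exactly double that row in all 12 libraries. A further 165 rows without a gene were left out, among them the ribosomal RNA region of chromosome 17. Together these rows held 52.9% to 64.8% of the counts of a library. Of the gene rows, 14293 carry an Ensembl identifier found in the GENCODE vM21 annotation of GRCm38, and all but 1 of these overlap their gene on the stated strand. Positions are those of the table, on mm10, and locations in a gene are the table's own unless GENCODE is named. The 5' UTR and 3' UTR of the table do not always match GENCODE: 422 of 1136 rows called 5' UTR and 1419 of 6700 called 3' UTR lie in coding exons there. Rows of genes with near-identical copies, such as ribosomal proteins with many pseudogenes, are uncertain because the handling of reads that map to several places is not given.

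Totals over all peaks, with values of Intergenic rows halved, were 12472784 to 14044464 per library, and totals over gene rows 4688215 to 6374892. Each gene row was tested as 1 feature with edgeR 4.0.16 (R 4.3.3), using TMM scaling, filterByExpr, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. The filter kept 14106 features. The 4 stages shared 1 fit without a replicate block. The common biological coefficient of variation was 0.342. The labels do not say whether replicates are separate animals, so p-values measure only the spread between these libraries. On simulated counts with 200 changed features, the same procedure recovered 21% to 30% of 3-fold changes and 1% to 6% of 2-fold changes, depending on the comparison. A feature that did not pass may therefore still have changed. Of the simulated calls, 8% were false at E13.5 against E11.5 (2 of 25), 12% at E17.5 against E11.5 (3 of 25), 3.3% at E15.5 against E13.5 and 2.9% at E17.5 against E15.5. With only 25 to 35 simulated calls the cut-off on p was stricter than in the data with 2433, 1843 or 7322 calls. The recovery given is thus not that of those 3 comparisons. Values are given as log2 change ± standard error, or as CPM (edgeR's scaled counts, after TMM) with the SD over 3 libraries. Where all 3 libraries of a stage had 0 counts, the fold is a lower bound against a floor of 3 counts over the 3 libraries. With 1 to 3 counts it is a ratio with a 95% exact binomial interval. Floors and intervals cover counting error only.

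The genes named were chosen by a rule fixed before the data were examined. For each comparison it takes the 10 features with the largest rise and the 10 with the largest fall past the threshold whose 3 libraries of 1 stage all lie above the 3 of the other. Unnamed gene models and repeats of a gene were skipped. It adds the 4 measured members with the smallest p in each gene list past the threshold, and a fixed set that includes Stau2, Stau1, Prox1, Trim32, Bbs2, Eomes, Neurog2, Pax6, Sox2, Tbr1, Tubb3 and Actb. Some genes that the rule picks are not described here. The table holds no gene row for Prox1, Trim32, Neurog2, Tubb3 or Actb.

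Counts were summed per gene for 28 gene lists, fixed at the same time as that rule. Of these, 22 had at least 5 measured members and were tested in the 4 comparisons with camera (limma 3.58.1) at a preset correlation of 0.01, and Benjamini-Hochberg adjustment ran over the 88 tests. On simulated data camera found the 1 shifted list and called 0 of 20 others. The simulated genes varied independently, so this cannot show false calls that come from correlation between genes of a list. In the data the estimated correlation reached 0.375, for ribosomal proteins at E17.5 against E11.5. Members are counted as risen or fallen by the edgeR test over all genes, and again adjusted over the list alone. The lists cover radial glia, early neuroepithelium and developmental timing, intermediate progenitors, deep-layer and upper-layer projection neurons, pan-neuronal differentiation, synapse and dendrite, axon guidance and cell adhesion, interneurons, and glia. They also cover meninges and mesenchyme, cell cycle, centrosome and microcephaly, primary cilium and Bardet-Biedl genes, reported Staufen2 cargo and partners, RNA-binding proteins, chromatin and transcription regulators, Notch, Wnt, Hedgehog and FGF signalling, cytoskeleton motors and transport, ribosomal proteins, nuclear oxidative phosphorylation, and nuclear and long noncoding RNAs. Not tested for lack of measured members were Cajal-Retzius cells, blood cells, endothelium and pericytes, microglia, mitochondrially encoded genes and replication-dependent histones.

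A row was called present at a stage when it reached 5 CPM in all 3 libraries, a level set after the table was seen. Present rows were compared between stages with an exact permutation test of the number per library and with hypergeometric tests of sharing. Locations of risen and fallen features were compared with Fisher's exact test (two-sided). Alternatives were DESeq2 1.42.0, no filter and a stricter filter, a replicate block, counts summed per gene, fits of the compared stages alone, a 2-fold minimum, each library left out in turn, and other presence rules. Other scalings, the libraries numbered 2 left out or as a batch term, rows called Intron left out, a GC offset per library and other presence levels were added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the rest.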

Results

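RNA bound to STAU2 was recorded at 4 stages of cortical development, from E11.5, when the cortex is mostly neuroepithelium, to E17.5. The question set by the design is how the bound RNAs change with stage. Each stage had 3 libraries. Totals over all peaks averaged 12541483 ± 73054 (SD, n = 3) at E11.5, 13612072 ± 280467 at E13.5, 13757794 ± 259989 at E15.5 and 13321130 ± 162579 at E17.5. The E11.5 libraries stood apart in composition. Rows called Intron held 61.0% ± 4.17 (SD, n = 3) of their gene-row counts, against 32.4% ± 1.65 at E13.5, 25.9% ± 3.09 at E15.5 and 27.7% ± 1.41 at E17.5. The intron row of Cmss1 alone held 1258258 to 1288024 counts in each E11.5 library. The 10 highest gene rows took 59.7% ± 4.30 of gene-row counts at E11.5 and 25% to 30.9% later, and the median gene row had 29 to 37 counts per library at E11.5 and 64 to 103 later. TMM scaling, whose factor averaged 0.528 ± 0.066 (SD, n = 3) at E11.5, sets the median change near 0. With scaling by the total of the gene rows, the median feature would shift by 1.21 on the log2 scale between E11.5 and E13.5 and by 1.2 between E11.5 and E17.5. All changes below are relative to the median feature.

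Over the 4 stages, 6578 of 14106 features changed (46.6%; edgeR F test). Scaling by the total of the gene rows would call 10297 and by the total over every peak 10659. The split that follows is that of the 6578. Their highest mean was at E11.5 for 2788, at E17.5 for 2695, at E13.5 for 614 and at E15.5 for 481. The first principal component held 56.3% of the variance and placed the stages in developmental order, with scores of -111.3 to -108.1 at E11.5, -15.2 to -9.4 at E13.5, 19.7 to 33.2 at E15.5 and 92.0 to 98.5 at E17.5. The plot of 6 genes shows that order for single RNAs. Hmga2, a chromatin protein of early progenitors, had 2034 ± 268 CPM (SD, n = 3) at E11.5 and 0.53 ± 0.92 at E17.5. Snap25, a synaptic vesicle fusion protein, had 10.4 ± 4.31 CPM at E11.5 and 544 ± 32.3 at E17.5.

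**Figure D1:**
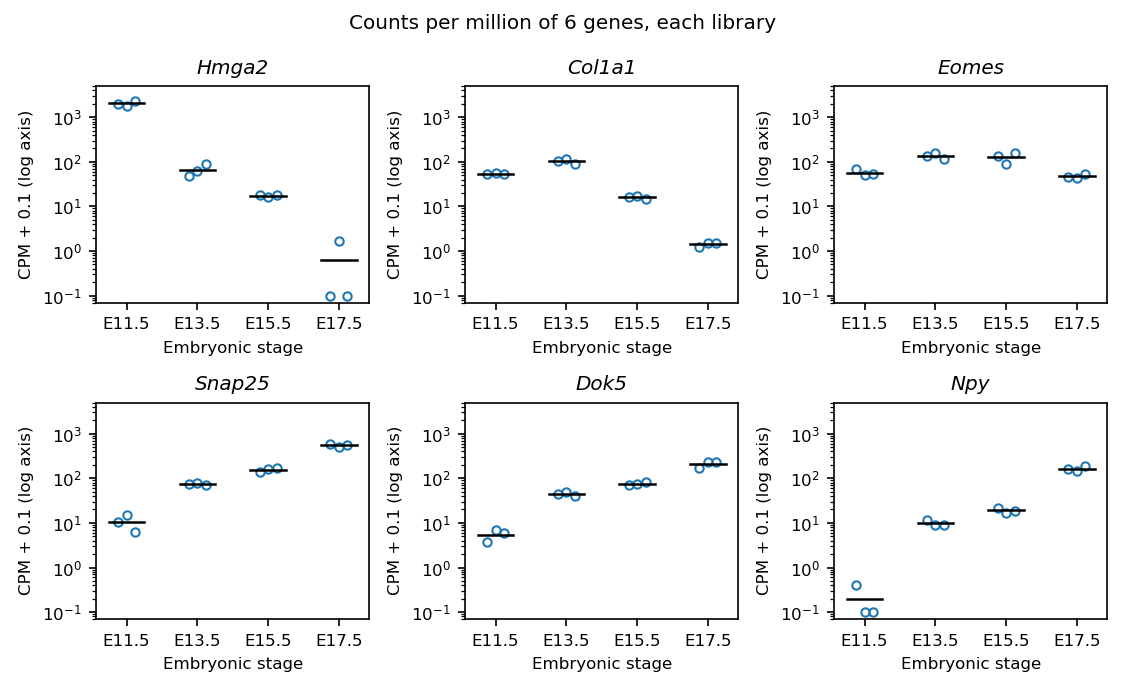
Scaled counts (CPM plus 0.1, log axis) of 6 genes, with all peaks of a gene summed, at the 4 embryonic stages on the horizontal axis. Each circle is 1 library (3 per stage) and each line the mean of a stage. Hmga2 falls from 2034 to 0.53 CPM and Snap25 rises from 10.4 to 544 CPM between E11.5 and E17.5.

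At 5 CPM in all 3 libraries, 9221 rows (5618 genes) were present at E11.5, 9635 (5842 genes) at E13.5, 9582 (5847 genes) at E15.5 and 9362 (5775 genes) at E17.5. The number per library was 10710 ± 129 (SD, n = 3), 10865 ± 19.5, 10859 ± 113 and 10555 ± 51.9 in the same order, and it differed between stages (exact permutation test over 15400 splits, two-sided, p = 0.0121). The order of the stages turns with the rule for presence: most rows were present at E15.5 in at least 2 of 3 libraries (10982), at E11.5 in any library (12044) and at E17.5 with 10 CPM, a level added after seeing the data (6519). Of the 14297 rows, 6848 (47.9%) were present at every stage, 2088 at 3 stages, 1252 at 2, 1640 at 1 and 2469 at none. The number at every stage depends on the level: it was 4034 at 10 CPM and 10308 at 2 CPM, levels added after seeing the data. Rows present at a single stage numbered 744 at E11.5, 155 at E13.5, 120 at E15.5 and 621 at E17.5. E13.5 and E15.5 shared 8866 rows (85.7% of those present at either), against 6458 for independent lists. E11.5 and E17.5 shared 7199 (63.2%), against 6038. All 6 pairs shared more than independent lists would (hypergeometric tests, log10 of p between -1905.3 and -392.6). Presence is a cut on abundance over the same merged peaks, so abundant rows tend to pass at any stage. These p-values therefore do not test whether binding is shared.

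From E11.5 to E13.5, RNAs of neuronal differentiation rose and RNAs of early progenitors fell. The largest rises were of RNAs with 0 counts in the 3 E11.5 libraries. Sez6, a neuronal membrane protein, was at least 60.8-fold higher at E13.5 (chromosome 11, 77931020 to 77931356, called 5' UTR but a coding exon in GENCODE), with 20.5 ± 12 CPM (SD, n = 3). Slc14a2, a urea transporter, was at least 31.6-fold higher (chromosome 18, 78184406 to 78184742, coding exon), and the neuronal splicing factor Rbfox3 at least 19.3-fold (chromosome 11, 118810916 to 118811350, 5' UTR). Fam163b was at least 20.4-fold higher (a call lost with counts summed per gene), Gipr, a gut hormone receptor, 18.6-fold, Bcan, a brain matrix proteoglycan, 17.8-fold, and the synaptic adhesion gene Lrfn5 13.9-fold, all as lower bounds. Lower bounds for 3 receptors were 13-fold for Sstr3, 12.6-fold for Rtn4r and 11.8-fold for Adora1. The fall of Lin28b, a repressor of let-7 maturation in early progenitors, was the largest, at -6.72 ± 0.52 (log2 ± SE; adjusted p = 2.19e-08), from 69.5 ± 25.4 to 0.63 ± 0.12 CPM in its 3' UTR (chromosome 10, 45379210 to 45379526). Falls of the homeobox genes Six2 and Six3 were -5.27 and -5.07 on the log2 scale, that of Hmga2 in its 5' UTR -5.12, and that of the growth factor Igf1 -4.59. The erythroid genes Ermap and Alas2 fell too (-5.28 and -4.54), as did the peptide hormone Apela (-4.96), Pir (-4.62) and the lipid transfer gene Pctp (-4.58). In all, 2433 of 14106 features changed (edgeR, adjusted p under 0.05), 1321 higher and 1112 lower at E13.5, in 1725 genes. The 2 sets of 3 libraries did not overlap for 34.0% of features, against 10% by chance. Scaling by the total of the gene rows would call 8325 features higher and 186 lower, and without E13.5 replicate 1 the count was 1530.

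Among the gene lists, 11 passed between E11.5 and E13.5. Axon guidance and cell adhesion rose most: 10 of 12 members rose and 1 fell (camera adjusted p = 2.62e-10), among them the adhesion molecules Dscam (375 against 2 counts, ratio 73.4, interval 20.2 to 608) and Cdh13 (3.74 ± 0.35), the ephrin receptor Epha5 (5.28 ± 0.50) and the transcription factor Nfib (3.49 ± 0.31). Of 15 pan-neuronal genes 10 rose and 0 fell (adjusted p = 1.24e-11). Neurod6, a transcription factor of cortical neurons, went from 19.1 ± 6.29 to 752 ± 146 CPM, L1cam, an axonal adhesion molecule, from 9.52 ± 1.81 to 293 ± 140, Rbfox3 rose by 3.52 ± 0.31 and Snap25 by 2.84 ± 0.29. Of 13 intermediate progenitor genes 8 rose and 0 fell (adjusted p = 1.57e-05), with Gadd45g at 2.44 ± 0.27, the Notch ligand Dll3 at 2.10 ± 0.26, and the neurogenic factors Neurod1 at 2.17 ± 0.32 and Nhlh1 at 1.64 ± 0.35. Of 10 upper-layer genes 4 rose and 1 fell (adjusted p = 0.00236), with Mdga1 at 3.08 ± 0.26, Dok5 at 3.05 ± 0.29 and Pou3f3 at 1.33 ± 0.28. These 4 lists also passed with an estimated correlation, as did early neuroepithelium and developmental timing, in which 5 of 7 fell and 1 rose (adjusted p = 8.26e-08). Its largest falls were of Lin28b (-6.74 ± 0.48), Hmga2 (-4.93 ± 0.51), Hmga1 (-2.06 ± 0.25) and Igf2bp2 (-2.24 ± 0.27), an RNA-binding protein. Adjusted over the list alone, the counts were 12 risen for pan-neuronal genes and 9 for intermediate progenitors, and the same for the other lists of these 5.

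Another 6 lists passed at E13.5 against E11.5 only with the preset correlation. Of 14 synapse and dendrite genes 8 rose and 0 fell (9 and 1 adjusted over the list alone; adjusted p = 0.145 with an estimated correlation). Shank1, a postsynaptic scaffold, rose by 1.97 ± 0.28. Counts over 3 libraries were 160 against 1 for Syn2 (ratio 62.7, interval 11 to 2490), 141 against 2 for Ppfia2 (27.6, interval 7.5 to 230) and 216 against 1 for Camk2b (84.6, interval 15 to 3356). Of 13 radial glia genes 5 rose and 1 fell (adjusted p = 0.179 with an estimated correlation), with Notch2 at 2.92 ± 0.31, Emx1 at 2.02 ± 0.41, Notch1 at 1.83 ± 0.38 and Fabp7 at 1.44 ± 0.31. That list lost its call without E11.5 replicate 3 (adjusted p = 0.118) or E13.5 replicate 2 (adjusted p = 0.108). Of 12 deep-layer genes 8 rose and 2 fell (adjusted p = 0.190 with an estimated correlation, and 0.0853 without E11.5 replicate 1), with Lmo3 at 1.84 ± 0.29, Sox5 at 1.44 ± 0.24, Nxph4 at 2.41 ± 0.43 and Ntsr1 at least 3.52-fold higher. Of 7 glia genes 4 rose and 1 fell (4 and 2 adjusted over the list alone; adjusted p = 0.128 with an estimated correlation). Bcan had 579 against 1 counts (ratio 227, interval 40.5 to 8969), Sparcl1 rose by 3.43 ± 0.40 and Nfia by 2.76 ± 0.32, while Olig2, a factor of oligodendrocyte precursors, fell by 2.26 (adjusted p = 0.0808 without E11.5 replicate 2, and lost with scaling by the total of the gene rows). Of 21 cytoskeleton and transport genes 8 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.0603 with an estimated correlation). Tubb2a rose by 1.75 ± 0.40, Dst by 1.19 ± 0.28 and Kif1a by 1.47 ± 0.39 (adjusted p = 0.0502 without E11.5 replicate 3), and Myo10 fell by 1.00, a direction that turned to 0.19 with scaling by the total of the gene rows. Of 7 ribosomal protein genes 2 fell, Rplp1 (-2.02) and Rps23 (-1.31; calls lost with scaling by the total of the gene rows), while Rpl3 stood at -0.85 ± 0.30 without passing, and the list median of -0.85 turned to 0.36 with scaling by the total of the gene rows. Adjusted over the list alone 4 fell (adjusted p = 0.326 with an estimated correlation), and the list's call was lost without E11.5 replicate 3 (adjusted p = 0.0915) or E13.5 replicate 2 (adjusted p = 0.130).

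**Figure D2:**
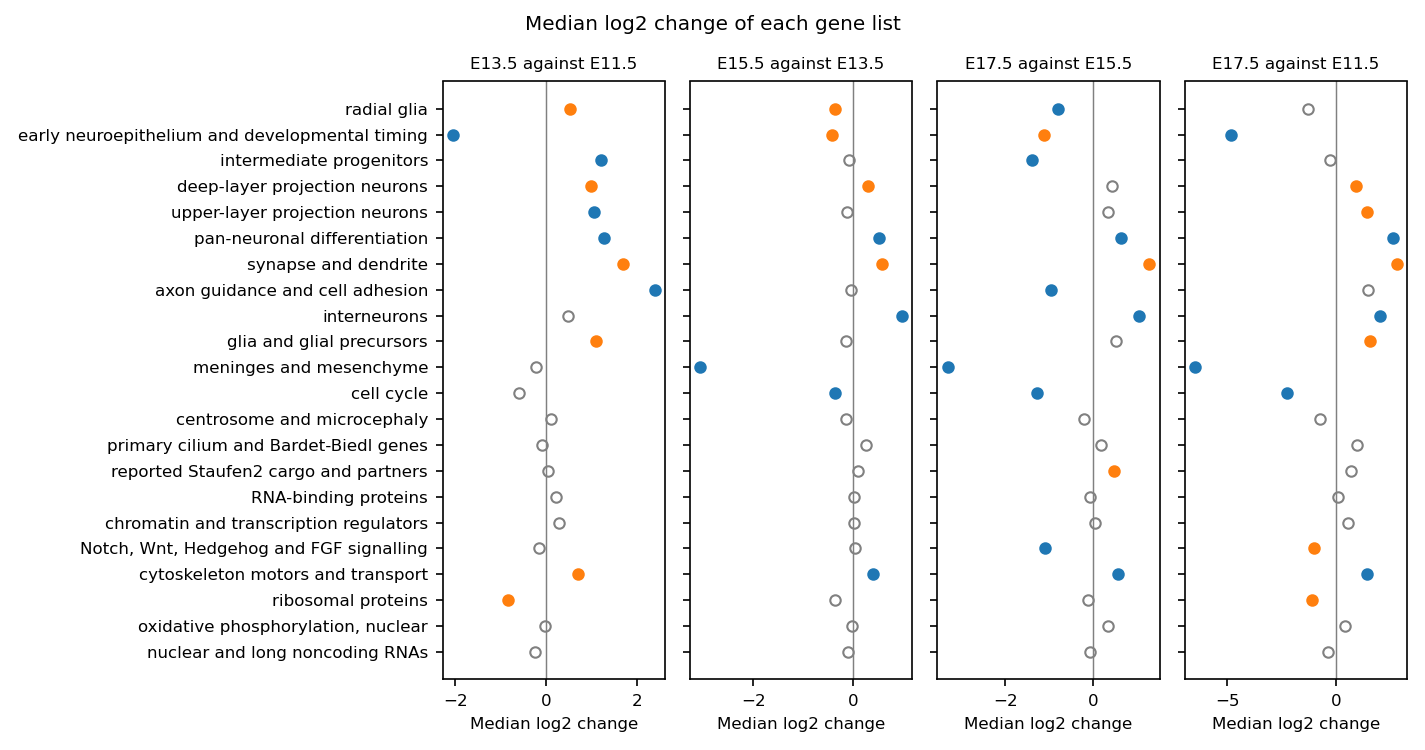
Median log2 change (horizontal axis, a separate scale in each panel) of the measured members of 22 gene lists (vertical axis) in the 4 stage comparisons. Blue points passed the camera test with the preset and with the estimated correlation, orange points with the preset correlation alone, and open grey points did not pass. The meninges and mesenchyme list has a median of -6.50 between E11.5 and E17.5 and pan-neuronal differentiation a median of 2.64.

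From E13.5 to E15.5, few features changed, and genes of meninges and mesenchyme fell as a list. Lum, a collagen-binding proteoglycan, fell by 4.11 on the log2 scale, from 20.1 ± 5.40 to 1.15 ± 0.39 CPM (SD, n = 3) in its 3' UTR (chromosome 10, 97572136 to 97572570; adjusted p = 1.98e-05). The collagen gene Col3a1 fell by 3.48 (chromosome 1, 45348790 to 45349224), from 47.6 ± 0.96 to 4.28 ± 2.17 CPM. Also lower were the mesenchymal factor Twist1 (-3.52), the homeobox gene Six2 (-3.90), the growth factor Bmp4 (-3.57), Serpinf1 (-3.43), Cped1 (-3.31), the zinc finger gene Zfp568 (-3.25) and the platelet chemokine Pf4 (-3.33). Dlk1, a Notch-like ligand, had 1 count at E15.5 against 31 (ratio 34.6, interval 5.76 to 1408). Only 6 features rose (18 with a replicate block): the calcium release channel gene Ryr3 (2.95 ± 0.58), the potassium channel regulator Abcc8 (2.95 ± 0.50), Dlx2 (2.08 ± 0.44), a transcription factor of interneurons, Sybu (2.0 ± 0.40), which links vesicles to kinesin, the vesicle coat gene Ap3b2 (1.93 ± 0.40) and Hs3st4 (1.82 ± 0.35), a heparan sulfate sulfotransferase. In all, 45 of 14106 features changed (edgeR), 6 higher and 39 lower, in 38 genes, and 965 had an unadjusted p under 0.05. The libraries did not overlap for 12% of features, against 10% by chance.

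Many single calls between E13.5 and E15.5 were lost without 1 or more of the 6 libraries, each left out in turn. The count fell to 25 without E13.5 replicate 1, 23 without E13.5 replicate 3, 19 without E15.5 replicate 1 and 25 without E15.5 replicate 2. The calls of Sybu and Pf4 were lost without any of the 6 libraries (adjusted p up to 0.173 and 0.152), those of Ap3b2, Dlk1 and Zfp568 without any of 5 (up to 0.224, 0.224 and 0.234), and those of Dlx2, Hs3st4 and Ryr3 without any of 4 (up to 0.233, 0.119 and 0.138). Serpinf1 was lost without any of 3 (up to 0.0769), Abcc8 without E13.5 replicate 1 (0.0569) and Twist1 without E13.5 replicate 3 (0.0528). Lum, Six2, Bmp4, Col3a1 and Cped1 passed without each of the 6. DESeq2 called 100 features, 33 higher and 67 lower.

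Among the lists, 9 passed between E13.5 and E15.5. Of 9 meninges and mesenchyme genes 8 fell and 0 rose (9 fell adjusted over the list alone), with a median of -3.07. The camera adjusted p was 8.64e-70 with the preset correlation and 5.82e-06 with an estimated one. The fallen genes include Lum (-4.11 ± 0.33), the collagen genes Col1a2 (-3.23 ± 0.30) and Col1a1 (-2.68 ± 0.23), and the proteoglycan Dcn (-3.07 ± 0.34). Of 7 interneuron genes 2 rose and 0 fell (4 risen adjusted over the list alone; adjusted p = 1.18e-05). Dlx2 rose by 1.31 ± 0.25 and Dlx5 by 1.40 ± 0.28, calls that 5 of the 6 left-out libraries each ended (adjusted p up to 0.110 and 0.125), while Npy stood at 0.99 ± 0.27 and Gad1, an enzyme of GABA synthesis, at 1.07 ± 0.35. Of 15 pan-neuronal genes 0 rose (3 adjusted over the list alone; adjusted p = 0.000956 for the list), with Snap25 at 1.06 ± 0.26, Mapt at 1.01 ± 0.32, Ina at 0.71 ± 0.22 and Ank3 at 0.55 ± 0.28. Of 21 cytoskeleton genes 0 passed (1 risen adjusted over the list alone; adjusted p = 0.000249 for the list), with Map6 at 1.09 ± 0.26, Tubb2a at 0.96 ± 0.39, Tubb2b at 0.87 ± 0.36 and Clasp2 at 0.66 ± 0.25. Of 15 cell cycle genes 0 passed, also adjusted over the list alone (adjusted p = 0.000235 for the list, which was lower), with Aspm at -0.91 ± 0.27, Cenpe at -0.88 ± 0.30, Bub1b at -0.70 ± 0.27 and Kif11 at -0.70 ± 0.31. These 5 lists passed with an estimated correlation too.

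The other 4 lists of the step from E13.5 to E15.5 passed only with the preset correlation. Of 14 synapse genes 1 rose, Shank1 (1.24 ± 0.26; 5 risen adjusted over the list alone; adjusted p = 0.0597 with an estimated correlation), and Camk2b stood at 1.72 ± 0.43, Dlg2 at 1.30 ± 0.38 and Dlg4 at 0.60 ± 0.21. The call of Shank1 was lost without any of 7 of the 12 libraries (adjusted p up to 0.205). Radial glia genes were lower as a list with 0 of 13 passing (3 fallen adjusted over the list alone; adjusted p = 0.10 with an estimated correlation, and 0.111 without E13.5 replicate 2), with Ednrb at -1.02 ± 0.31, Emx2 at -0.97 ± 0.31, Prom1 at -1.05 ± 0.33 and Sox2 at -0.78 ± 0.43. Early neuroepithelium genes were lower with 0 of 7 passing (3 fallen adjusted over the list alone; adjusted p = 0.0927 with an estimated correlation), with Hmga2 at -1.96 ± 0.46, Igf2bp2 at -0.68 ± 0.26, Hmga1 at -0.35 ± 0.25 and Lin28b at 14 against 1 counts (ratio 15.7, interval 2.38 to 663). Deep-layer genes were higher with 0 of 12 passing (1 risen adjusted over the list alone; adjusted p = 0.256 with an estimated correlation), with Ldb2 at 0.93 ± 0.25, Ntsr1 at 0.96 ± 0.45, Crym at 1.92 ± 1.02 and Fezf2 at 0.40 ± 0.23. The deep-layer call was lost without E13.5 replicate 1 (adjusted p = 0.132), E13.5 replicate 2 (0.161) or E15.5 replicate 2 (0.223).

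From E15.5 to E17.5, genes of pan-neuronal differentiation and of interneurons rose as lists, while those of progenitors, cell cycle and meninges fell. The largest rise was of Ptk2b, a calcium-regulated tyrosine kinase, by 5.43 ± 0.60 (log2 ± SE; adjusted p = 2.10e-05) in its 3' UTR (chromosome 14, 66153211 to 66153849). Nrgn, a postsynaptic calmodulin-binding protein, rose by 4.28 ± 0.51, from 10.2 ± 5.33 to 198 ± 31.6 CPM (SD, n = 3) in its 3' UTR (chromosome 9, 37544706 to 37545212). Tcerg1l rose by 4.86, the actin regulator Mical2 by 4.23, Fam43b by 4.13, the calcium-dependent membrane-binding gene Cpne5 by 4.03, the kinase Stk32c by 4.01, the homeobox gene Mkx by 3.92 and Olig2 by 3.89. The falls included Ttr, a thyroid hormone carrier made by choroid plexus, with -5.60 on the log2 scale, from 63.5 ± 25.4 to 1.30 ± 0.64 CPM (chromosome 18, 20666378 to 20666782, coding exon), and Neurog1, a proneural factor, with -5.06, from 40.1 ± 18.8 to 1.19 ± 0.93 CPM (chromosome 13, 56251048 to 56251392). Counts at E15.5 against E17.5 were 310 against 1 for the long noncoding RNA Rmst (ratio 226, interval 40.3 to 8972), 134 against 1 for Prelp (97.9, interval 17 to 3895), 102 against 1 for Apod (74.5, interval 13 to 2971) and 164 against 3 for the Hmga2 3' UTR (39.9, interval 13.4 to 196). At 0 counts in the E17.5 libraries, the tight junction gene Cldn9 was at least 14.9-fold lower, Lum 6.82-fold, Nhs 5.84-fold and the intron row of Lrrc1 4.14-fold, the last lost without E15.5 replicate 1, E17.5 replicate 1 or E17.5 replicate 3 (adjusted p up to 0.0707). In all, 1843 features changed (edgeR), 831 higher and 1012 lower, in 1380 genes. Scaling by the total of the gene rows would call 582 higher and 1384 lower, and by the total over every peak 372 and 2303. The libraries did not overlap for 30.5% of features, against 10% by chance. The count was 1054 without E17.5 replicate 1, 1160 without E17.5 replicate 3 and 1198 without E15.5 replicate 3.

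Of the lists, 12 passed between E15.5 and E17.5, 7 lower and 5 higher. Of 13 intermediate progenitor genes 10 fell and 1 rose (camera adjusted p = 2.02e-08): Neurog1 (-4.78 ± 0.41), Nhlh1 (-3.84 ± 0.38), Heg1 (-2.33 ± 0.34) and the small GTPase gene Rnd2 (-2.26 ± 0.36) are among them. Of 13 radial glia genes 6 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 5.48e-05), with Emx2 lower by a log2 change of -2.17 ± 0.32, Prom1 by -2.24 ± 0.36, Notch2 by -1.74 ± 0.28 and Notch1 by -2.12 ± 0.38. Of 15 cell cycle genes 10 fell (11 adjusted over the list alone) and 0 rose (adjusted p = 1.98e-06), with Aspm at -1.79 ± 0.29, Ccnd2 at -2.20 ± 0.39, Bub1b at -1.67 ± 0.30 and Plk1 at -1.27 ± 0.27. Of 16 genes of Notch, Wnt, Hedgehog and FGF signalling 8 fell (11 adjusted over the list alone) and 0 rose (adjusted p = 4.26e-06), with Tcf7l1 at -3.10 ± 0.30, Smo at -2.10 ± 0.27, Gli3 at -2.08 ± 0.29 and Notch1 again. Of 12 axon guidance genes 6 fell and 0 rose (8 and 1 adjusted over the list alone; adjusted p = 0.000514), with Dcc, a netrin receptor, at -3.06 ± 0.36, Efnb1 at -1.82 ± 0.27, Epha4 at -1.54 ± 0.31 and Cdh13 at -1.32 ± 0.27. Of 9 meninges genes 6 fell (7 adjusted over the list alone) and 0 rose (adjusted p = 1.10e-08), with Col1a1 at -3.57 ± 0.28, Col1a2 at -3.83 ± 0.41, Igf2 at -2.61 ± 0.32 and Dcn at -3.31 ± 0.45. Of 7 early neuroepithelium genes 4 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.128 with an estimated correlation), with Hmga2 at -5.03 ± 0.65, Igf2bp2 at -1.92 ± 0.27, Hmga1 at -1.11 ± 0.25 and Sall4 at -3.67 ± 0.86.

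The 5 lists that were higher at E17.5 than at E15.5 held genes of neurons. Of 7 interneuron genes 5 rose (6 adjusted over the list alone) and 0 fell (adjusted p = 1.15e-05). Npy, a neuropeptide, went from 19.1 ± 2.62 to 164 ± 20.6 CPM (SD, n = 3), Gad1 rose by 2.19 ± 0.33 and Dlx2 by 1.06 ± 0.24. Of 15 pan-neuronal genes 7 rose (8 adjusted over the list alone) and 0 fell (adjusted p = 0.00141), with Snap25 at 1.81 ± 0.26, the microtubule genes Mapt at 1.92 ± 0.33 and Stmn2 at 1.72 ± 0.30, and the neurofilament gene Nefm at 1.68 ± 0.36. Of 21 cytoskeleton genes 9 rose (10 adjusted over the list alone) and 1 fell (adjusted p = 0.000345), with Map6 at 2.31 ± 0.26, Apc2 at 2.19 ± 0.34, Dst at 1.33 ± 0.27 and Tubb2a at 1.84 ± 0.40. Of 14 synapse genes 8 rose (9 adjusted over the list alone) and 0 fell (adjusted p = 0.0702 with an estimated correlation), with the kinase subunit Camk2b at 3.13 ± 0.44, Shank1 at 1.83 ± 0.26, the NMDA receptor subunit Grin1 at 2.56 ± 0.39 and Ppfia2 at 1.76 ± 0.33. Of 14 reported Staufen2 cargo RNAs and partners 3 rose, Camk2b, Camk2a (1.93 ± 0.36) and Ddx1 (1.32 ± 0.32), also adjusted over the list alone, and 0 fell (adjusted p = 0.0805 with an estimated correlation). Bbs2 stood at 1.15 ± 0.43 without passing.

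Between the ends of the series, E11.5 and E17.5, genes of pan-neuronal differentiation and of interneurons rose as lists, and those of early neuroepithelium, meninges and cell cycle fell. With 0 counts at E11.5, the lower bounds were 296-fold for Fam163b (3' UTR, chromosome 2, 27111547 to 27112119), 148-fold for Gipr, 141-fold for Npy (3' UTR, chromosome 6, 49829239 to 49829705), 89.6-fold for Trim67, 78.1-fold for Adora1, 69.6-fold for Arpp21, 58.8-fold for Ptk2b, 54.4-fold for Hivep3 and 48.4-fold for Ryr3. The exon row of Camk2b (chromosome 11, 5982299 to 5982703) had 5060 counts at E17.5 against 1 (ratio 2464, interval 442 to 97333). With 0 counts at E17.5, Six2 (3' UTR, chromosome 17, 85684255 to 85685053) was at least 1064-fold lower, Hmga2 (5' UTR, chromosome 10, 120476338 to 120476482) at least 466-fold, the neural crest factor Tfap2b 176-fold, Lum 138-fold, Blcap 84.9-fold, Lrrc1 81.5-fold, Dlk1 71.2-fold, the Wnt agonist Rspo1 66.4-fold and Igf1 60.9-fold, all as lower bounds. The fall of Blcap was of its 5' UTR row, since counts summed over the gene gave 0.35 and no call. In all, 7322 features changed (edgeR), 3646 higher and 3676 lower at E17.5, in 4633 genes. The libraries did not overlap for 57.0% of features, against 10% by chance. Scaling by the total of the gene rows would call 7817 higher and 1301 lower.

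Of the lists, 12 passed between E11.5 and E17.5. Meninges and mesenchyme genes fell most, all 9 of 9, also adjusted over the list alone (camera adjusted p = 5.37e-13), with a median of -6.50. The growth factor Igf2 went from 8204 ± 294 to 23.3 ± 5.38 CPM (SD, n = 3), and Col1a1 (-5.32 ± 0.29), Col1a2 (-7.01 ± 0.40) and Lum (-7.34 ± 0.45) fell as well. Of 15 cell cycle genes 13 fell and 0 rose, also adjusted over the list alone (adjusted p = 3.89e-05), with Bub1b at -2.99 ± 0.31, Cenpe at -2.87 ± 0.33, Aspm at -2.48 ± 0.30 and Ccnb1 at -2.92 ± 0.39. Of 7 early neuroepithelium genes 5 fell and 1 rose, also adjusted over the list alone (adjusted p = 1.67e-06), with Hmga2 at -11.91 ± 0.74, Igf2bp2 at -4.84 ± 0.31, Hmga1 at -3.51 ± 0.27 and Lin28b at 586 against 3 counts (ratio 410, interval 140 to 1995). Of 15 pan-neuronal genes 13 rose and 0 fell, also adjusted over the list alone (adjusted p = 7.46e-10), with Snap25 at 5.71 ± 0.32, Mapt at 6.19 ± 0.41, Rbfox3 at 4.74 ± 0.32 and Neurod6 at 5.34 ± 0.39. Of 21 cytoskeleton genes 18 rose and 2 fell, also adjusted over the list alone (adjusted p = 3.52e-05), with Map6 at 4.11 ± 0.30, Dst at 3.05 ± 0.29, Tubb2a at 4.55 ± 0.45 and Apc2 at 3.79 ± 0.42. Of 7 interneuron genes 6 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.000248), with Npy at 2963 against 1 counts over the gene (ratio 1411, interval 253 to 55752), the neuropeptide Sst at 6.71 ± 0.60 and Gad1 at 3.73 ± 0.40.

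The other 6 lists of E17.5 against E11.5 passed only with the preset correlation. Of 14 synapse genes 10 rose (11 adjusted over the list alone) and 0 fell (adjusted p = 0.0679 with an estimated correlation): Shank1 by 5.04 ± 0.31, while counts over 3 libraries were 751 against 2 for Ppfia2 (ratio 179, interval 49.3 to 1479) and 461 against 2 for Dlg2 (ratio 110, interval 30.2 to 909). Of 10 upper-layer genes 6 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.0541 with an estimated correlation), with Dok5 at 5.32 ± 0.31, Mdga1 at 3.13 ± 0.26 and Pou3f3 at 2.30 ± 0.28. Of 12 deep-layer genes 8 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.206 with an estimated correlation, and 0.0525 without E11.5 replicate 1). Ldb2 rose by 3.52 ± 0.28, Lmo3 by 3.14 ± 0.30 and Ntsr1 at least 42.5-fold, while Foxp2 fell by 1.57, a call lost with scaling by the total of the gene rows, as was that of Sox9 below. Of 7 glia genes 5 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.186 with an estimated correlation), with Sparcl1 at 3.65 ± 0.40, Sox9 at -1.50 ± 0.29, Bcan at 583 against 1 counts (ratio 278, interval 49.6 to 10985) and Sox10 at 149 against 3 (ratio 23.7, interval 7.94 to 116). Of 16 signalling genes 8 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.0768 with an estimated correlation). Tcf7l1 (-4.16), Gli3 (-4.07), Smo (-3.65) and Tcf7l2 (-3.72) fell, while the list median of -1.01 turned to 0.22 with scaling by the total of the gene rows. Of 7 ribosomal protein genes 5 fell, also adjusted over the list alone (adjusted p = 0.380 with an estimated correlation), among them Rplp1 (-3.22), Rps23 (-1.88) and Rpl27 (-1.08), and the list median of -1.08 turned to 0.13 with that scaling, which also ended the call of Rps23 and turned Rpl27 to 0.13. The ribosomal call was lost without E11.5 replicate 3 (adjusted p = 0.0915), E15.5 replicate 3 (0.0517) or E17.5 replicate 2 (0.0695).

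The 44 other tests of lists did not pass. At E13.5 against E11.5 these included meninges and mesenchyme (2 of 9 rose and 3 fell; adjusted p = 0.385) and cell cycle (1 of 15 rose and 1 fell; adjusted p = 0.341). At E13.5 against E11.5, of 26 chromatin regulators 9 rose and 3 fell (11 and 4 adjusted over the list alone; adjusted p = 0.0806). Between E11.5 and E17.5, 13 of these 26 rose and 5 fell (adjusted p = 0.344), 7 of 23 RNA-binding protein genes rose and 8 fell (adjusted p = 0.983), 3 of 18 centrosome genes rose and 8 fell (adjusted p = 0.206), and 6 of 13 cilium genes rose and 2 fell (6 and 3 adjusted over the list alone; adjusted p = 0.502). In the same comparison 5 of 12 genes of nuclear oxidative phosphorylation rose (4 adjusted over the list alone) and 0 fell (adjusted p = 0.408), 1 of 8 long noncoding RNAs rose and 3 fell (adjusted p = 0.408), and 6 of 14 reported Staufen2 cargo RNAs and partners rose and 3 fell (7 and 3 adjusted over the list alone; adjusted p = 0.147). Genes of intermediate progenitors went up and down again: 4 of 13 rose and 6 fell between E11.5 and E17.5 (adjusted p = 0.502). The list of oxidative phosphorylation came close at E17.5 against E15.5, with 3 of 12 risen (adjusted p = 0.0513), and passed without E13.5 replicate 1 (0.0469), E13.5 replicate 2 (0.0498), E15.5 replicate 1 (0.0281) or E17.5 replicate 2 (0.0348). Without 1 library, 3 other tests passed: axon guidance at E17.5 against E11.5 without E11.5 replicate 2 (0.0434), centrosome at E15.5 against E13.5 without E15.5 replicate 3 (0.0348), and ribosomal proteins in that comparison without E13.5 replicate 2 (0.00539) or E15.5 replicate 1 (0.0167).

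Stau2 RNA itself lay under 6 peaks. The distal 3' UTR peak (chromosome 1, 16229183 to 16229636) rose by 1.99 ± 0.38 between E11.5 and E17.5 (edgeR adjusted p = 0.000155), from 7.71 ± 2.38 to 30.5 ± 8.36 CPM (SD, n = 3), while the other 5 ranged from -0.33 ± 0.41 to 0.61 ± 0.43 without passing. Counts summed over Stau2 did not pass. Stau1, its paralog, stood at 0.70 ± 0.40 in its 3' UTR and 0.09 ± 0.40 in its 5' UTR, neither past the threshold. Bbs2, a cilium gene, rose in its 3' UTR (2.80 ± 0.53) and in a coding exon (2.29 ± 0.78), the latter lost without E11.5 replicate 3 or E17.5 replicate 3 (adjusted p up to 0.224).

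Eomes (Tbr2), the marker of intermediate progenitors, rose and then fell. Its 3' UTR peak (chromosome 9, 118485096 to 118485240) went from 51.5 ± 10.3 CPM (SD, n = 3) at E11.5 to 120 ± 27.2 at E13.5 (1.22 ± 0.35; edgeR adjusted p = 0.0179), 112 ± 32.0 at E15.5 and 41.6 ± 2.64 at E17.5 (-1.43 ± 0.35 against E15.5; adjusted p = 0.00882). The rise was lost without E11.5 replicate 2, E11.5 replicate 3 or E13.5 replicate 2 (adjusted p up to 0.0763). Its exon peak rose by 1.52 ± 0.38 and fell by 1.33 in the same steps, the fall lost without E15.5 replicate 3, E17.5 replicate 1 or E17.5 replicate 2 (adjusted p up to 0.0715). Pax6 and Sox2 mark radial glia. Pax6 fell by 1.83 between E15.5 and E17.5, which was lost without E15.5 replicate 2, E17.5 replicate 1 or E17.5 replicate 3 (adjusted p up to 0.239), and by 1.24 between E11.5 and E17.5, lost without E11.5 replicate 2 or those 2 E17.5 libraries (up to 0.341). Sox2 fell by 1.55 between E11.5 and E17.5. With scaling by the total of the gene rows the calls of Pax6 and Sox2 at E17.5 against E11.5 were lost (-0.02 and -0.37). Tbr1, a marker of deep-layer neurons, moved apart by peak. Its 3' UTR peak rose by 1.03 ± 0.34 between E11.5 and E17.5 (lost without E11.5 replicate 3 or E17.5 replicate 1, adjusted p up to 0.0589). An exon peak (chromosome 2, 61806397 to 61806541), classed with GENCODE as neither coding exon nor UTR, fell by 2.77. That exon peak was low, with 7.02 ± 1.74 CPM at E11.5 and 1.02 ± 0.52 at E17.5.

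Peaks in 3' UTRs were more common among features that rose than among those that fell. Of all gene rows, 6700 (46.9%) were called 3' UTR, 5918 (41.4%) exon, 1136 (7.9%) 5' UTR and 543 (3.8%) intron. Rows called 3' UTR were 49.4% (95% exact binomial interval 48.3 to 50.4) of those present at E11.5, 50.2% at E13.5, 51.1% at E15.5 and 52.1% (51.1 to 53.1) at E17.5. Of the features that rose between E11.5 and E17.5, 54.3% were called 3' UTR, against 41.8% of those that fell (odds ratio 1.66, interval 1.51 to 1.82; Fisher's exact test, two-sided, p = 7.66e-27, adjusted over 4 locations 3.06e-26). For 5' UTR the shares were 5.54% and 11% (odds ratio 0.466, interval 0.389 to 0.557), for exon 37.9% and 43.0% (0.809) and for intron 2.25% and 4.03% (0.548). Features of 1 gene are not independent. All features also come from the same 3 libraries per stage, so a shift of whole libraries would move many together. These p-values and intervals therefore do not measure the spread between libraries. With the highest peak of each gene alone, the odds ratio for 3' UTR was 1.76, and with the classes of GENCODE, chosen after seeing the data, 1.55.

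**Figure D3:**
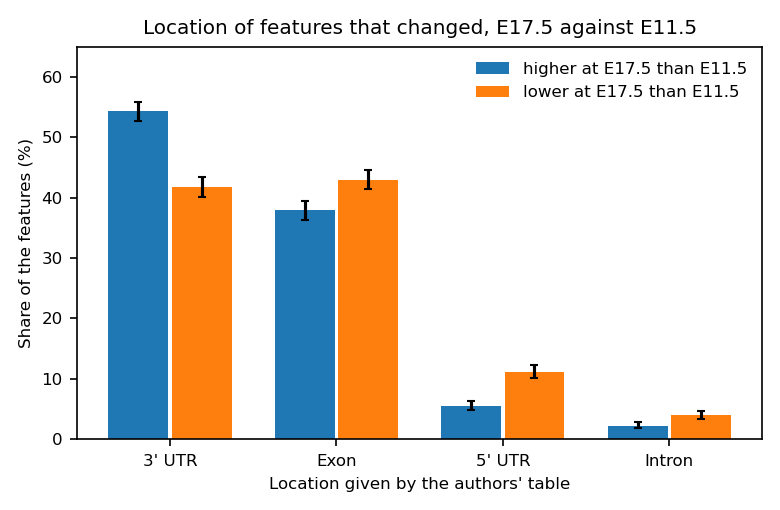
Share (%) of the features that were higher (blue, 3646 features) or lower (orange, 3676 features) at E17.5 than at E11.5 in each location given by the table on the horizontal axis. Error bars are 95% exact binomial intervals over features and do not cover the spread between libraries. Rows called 3' UTR make up 54.3% of the higher and 41.8% of the lower features.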

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

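The tests of the amount of meningeal tissue, of scaling, of larger spread, of the libraries numbered 2 and of regrouped libraries were chosen after the results were seen. The tests of GC content, loss of 5' ends and longer 3' UTRs were written before their own values were computed, though the rule written for loss of 5' ends was not the one applied.

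Outside the comparisons, 114 peaks recorded only as Intergenic had at least 10 counts in every library after halving, and were noted because no gene row covers them. The values deposited for these rows are all even and were halved here, since Intergenic rows beside a gene row hold exactly double its count. Of the 283 such peaks, 15 held 96.6% to 97.9% of these counts. The highest, on chromosome 6 (3201298 to 3201732), had 388541 to 600659 counts per library at E11.5 and 900183 to 1489641 at E17.5.

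In the median gene, peaks in 3' UTRs gained on peaks in 5' UTRs between E11.5 and E17.5. The within-gene change was 0.28 on the log2 scale (interval 0.20 to 0.33, 594 genes, 68.5% up). Intervals in this paragraph resample genes and do not cover the spread between libraries. Library medians of the ratio overlapped, with 0.663 to 0.969 at E11.5 and 0.941 to 1.167 at E17.5. Over the 4 stages they did not differ past the threshold (exact permutation test, n = 3 per stage, p = 0.081). GC content as the whole cause is argued against, since after a GC offset per library the change was still 0.28 (0.20 to 0.35). With that offset the library medians were 0.706 to 0.856 at E11.5 and 0.973 to 1.103 at E17.5 (same permutation test over 4 stages, p = 0.053). Loss of 5' ends cannot be told apart from the rest. Exon pairs over the same distance predict 0.15 (0.11 to 0.19), an interval that ends below that of the change. By the rule written beforehand this counts against loss of 5' ends as the whole cause. The rule also assumed a straight line with distance and was set aside for that reason. Longer 3' UTRs at later stages may contribute, since the farthest 3' UTR peak of a gene gained 0.09 (0.06 to 0.14) on the nearest, which loss of 5' ends predicts too, and a change of binding with stage is untested.

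The 9 markers of meninges and mesenchyme fell, with a median of -6.50 on the log2 scale, between E11.5 and E17.5. Scaling between libraries as the whole cause is argued against, since the weaker of 2 scalings by library totals gave -5.29. If the amount of meningeal tissue varied between dissections of a stage, these markers would vary together within stages. Their mean correlation within stages was 0.005, at percentile 59.3 of 10000 random lists, which cannot be told apart from chance with 3 libraries a stage. A steady difference between stages in how much meninges was taken, or in the tissue itself, stays open, and Igf2 and Col4a1 of this list are also made by other cells of the brain.

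Fewer features changed between E13.5 and E15.5 (45) than in the steps before (2433) and after (1843). A first test looked for larger spread between the libraries of E13.5 and E15.5. Biological coefficients of variation, each stage alone, were 0.337 and 0.344, against 0.347 at E11.5 and 0.339 at E17.5. Spread at these stages was thus close to that at the others, which argues against larger spread as the whole cause. A test picked after that one argues the same way, since noise widens changes between stage means. Their interquartile range was 0.544 (0.557 to 0.68 with 1 library left out). It was at least 1.12 and 1.02 in the steps before and after with 1 library left out. The libraries numbered 2, which hold more antisense counts (median over peaks 6.53% to 8.76%, against 1.82% to 3.92%), are argued against as the cause, since without them the counts were 105, 2221 and 1911. A smaller change of the cortex in that step is a hypothesis these data leave open.

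When the 12 libraries were split at random into 4 groups of 3, 1 of 100 splits, the real grouping, gave as many changed features over the 4 stages, which argues against chance: the real count was 6578 and the highest other 2763. Each comparison of 2 stages allows 10 splits, too few for a share under 0.05, and in each only 1 split, the real one, gave as many features. The real counts were 2433, 45, 1843 and 7322 and the highest other was 0 in each. Adjusted within each comparison rather than over all 88 tests, the real numbers of gene lists past the threshold were 11, 9, 13 and 12, and the highest other splits gave 5, 4, 10 and 8.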

How the results depend on the processing

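Comparisons with input were not run, alternatives with another pseudocount do not apply to counts, and a fit of 2 stages alone does not apply to the test over 4 stages. Where an alternative tested the same features, no feature was called in the opposite direction. Among the features above the median of mean CPM, 1509, 25, 990 and 3706 changed in the order of the comparisons and 3421 over the 4 stages, fewer since 7053 were tested. With 1 value per gene 4549 genes changed between E11.5 and E17.5 and 4228 over the 4 stages, and between E13.5 and E15.5 14 rose and 39 fell. DESeq2 called 100 features between E13.5 and E15.5, 33 higher. Camera with an estimated correlation called 25 of 88 list tests in place of 44, and fry 62.

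A replicate block called 75 features between E13.5 and E15.5, 18 higher and 57 lower, and changed no count of lists. Libraries of different stages share a number but the labels do not say that they share an animal or a batch. Of the 6 pairs of libraries numbered 2 all 6 correlated above 0.1 (0.14 to 0.52), against 5 of 12 other pairs with the same number, and 4 of 12 libraries correlated best with their own number. The libraries numbered 2 had the lowest score of their stage on component 3 (-53.3, -20.3, -34.9 and -43). Replicate 2 as a batch term, chosen after seeing the data, gave 74 in that comparison, and leaving out the libraries numbered 2 gave 105. Without those libraries the calls of Ryr3, Ap3b2, Dlx2 and Dlx5 (summed per gene) and Shank1 between E13.5 and E15.5 were lost, as were those of the Eomes 3' UTR peak in the first step and its exon peak in the last and Olig2 in the first.

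Scalings by library totals were chosen after seeing the data. By the total of the gene rows 8511 features changed between E11.5 and E13.5 (8325 higher, 186 lower) and 10297 over the 4 stages, and by the total over every peak 8745 (8570 higher, 175 lower) and 10659. The split into higher and lower was 9 and 27 between E13.5 and E15.5 with both. It was 582 and 1384, and 372 and 2303, between E15.5 and E17.5, and 7817 and 1301, and 6856 and 1607, between E11.5 and E17.5. Upper-quartile factors gave 666 and 1266 between E15.5 and E17.5. The median feature shifted by 1.26 (E13.5 against E11.5), 0.15, -0.42 and 0.97 by the total over every peak, by 0.19 and -0.19 in the middle steps by the total of the gene rows, and by -0.12 and -0.17 at E17.5 against E15.5 and E11.5 with upper-quartile factors.

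Some single genes turned direction. With counts summed per gene the Tbr1 exon peak gave 0.97 (E13.5 against E11.5) and 0.83 (E17.5 against E11.5), and Blcap 0.35. By the total of the gene rows, E13.5 against E11.5 gave 1.15 for Sox2, 1.1 for Stau1, 0.94 for a Stau2 peak and 0.19 for Myo10, and E17.5 against E11.5 gave 0.85 for Eomes and 0.13 for Rpl27. By the total over every peak, E13.5 against E11.5 gave 1.2 for Sox2, 1.16 for Stau1, 0.99 and 1.05 for 2 Stau2 peaks and 0.24 for Myo10.

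Leaving out each library in turn gave 1530 to 1942, 19 to 31, 1054 to 1497 and 6296 to 6682 changed features in the order of the comparisons, 5697 to 6677 over the 4 stages, and 41 to 46 lists. Present features at E11.5, E13.5, E15.5 and E17.5 were 5872, 6156, 6114 and 5901 above the median peak score, and 5618, 5842, 5847 and 5775 as genes, of which 4480 were present at every stage. At 10 CPM there were 6061, 6359, 6410 and 6519 in the order of the stages, so E17.5 in place of E13.5 had most, and 4034 at every stage, and at 2 CPM 10308 at every stage. Leaving out a library gave 9221 to 9907, 9635 to 10141, 9582 to 10222 and 9362 to 9863 present features by stage, and 6869 to 7100 at every stage.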

Other observations

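Of the lists too small to test, Cajal-Retzius cells had 4 measured members, which moved apart. Reln, secreted by these cells, went from 2.33 ± 2.39 CPM (SD, n = 3) at E11.5 to 42.0 ± 3.20 at E13.5 (log2 change 4.07 ± 0.46, edgeR adjusted p = 1.83e-05) and 50.2 ± 11.4 at E17.5. Ebf2, a transcription factor of these cells, fell from 30.0 ± 14.2 CPM to 0.56 ± 0.10 between E11.5 and E17.5 (-5.70 ± 0.49), past the threshold in each step. Calb2 rose by 2.06 ± 0.49 and Cacna2d2 by 1.38 ± 0.30 between those stages. Alas2, an enzyme of heme synthesis and the 1 measured gene of blood cells, fell from 12.4 ± 3.91 CPM at E11.5 to 0.06 ± 0.1 at E17.5. Of 4 genes of endothelium and pericytes, Tek fell by 3.37, Cdh5 by 3.63 and Vtn by 1.94, while Kdr did not pass (-0.59 ± 0.45). Among genes of microglia, P2ry12 rose by 1.79 ± 0.64, while Csf1r (0.71 ± 0.45) and C1qb (-0.07 ± 0.48) did not pass. Mitochondrially encoded genes and replication-dependent histones had 0 measured members.

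Peaks of 1 gene seldom moved in opposite directions. Of 3415 genes with 2 or more peaks, 1611 had 2 or more changed peaks between E11.5 and E17.5, and 53 of these changed both ways. Tbr1 was among them, through an exon peak with only 18 counts over the 3 E17.5 libraries. The log2 ratio of its 3' UTR peak to its exon peak was 2.80 ± 0.09 (SD, n = 3) at E11.5, 4.56 ± 0.08 at E13.5, 5.97 ± 0.39 at E15.5 and 6.17 ± 0.33 at E17.5 (exact permutation test, p = 0.000325, for a gene picked after seeing the data).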
